A study of Mus musculus with 12 samples.

How the data were processed

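The series holds bulk RNA sequencing of primary chondrocytes from the epiphyses of 5-day-old mice of 4 genotypes, with 3 samples of each: wild type (WT), Phlpp1 knockout, Phlpp2 knockout and Phlpp1/2 knockout. Per the labels' protocols, cells were released with collagenase, frozen, thawed and plated overnight in medium with serum before RNA was taken, and every sample was labelled female. The labels give the strain as C57BL6 for most samples, with other final digits for Phlpp2 KO 3 and all 3 Phlpp1/2 KO samples. They do not say whether a sample was 1 animal or a pool, and they name no batch or date.

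The values used were the deposited table of raw counts per gene, with no normalization. Per the submitters' processing notes, reads were converted with bcl2fastq 2.17, aligned with STAR 2.5.2b to the mm10 genome build and counted with featureCounts of Subread 1.5.2. The strand setting, the annotation release and the treatment of reads with several matches are not given in the sources used here. The table held 49315 genes, of which 174 had no symbol and carried 0.00419% of the counts. Positions came from the GENCODE vM21 annotation of the same build for 49056 genes. No column of per-sample values was left unused. Library totals ran from 21706337 to 33115345 counts, so that 1 count was worth 0.0295 to 0.0453 CPM.

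Counts were analysed with edgeR 4.0.16 in R 4.3.3. The filter of edgeR for low counts left 16565 genes for testing and removed 32750, and the tested genes held at least 99.91% of the counts of every library. Libraries were scaled with TMM factors. All 12 libraries entered 1 model with a term for genotype (8 residual degrees of freedom), and contrasts were tested with edgeR's quasi-likelihood test with robust estimation. P values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p under 0.05 were called. The common biological coefficient of variation was 0.105. Contrasts were the 6 pairs of genotypes and the interaction of both losses, which asks whether the log2 changes of the single knockouts add up to that of the Phlpp1/2 knockout. CPM used TMM-scaled library sizes, SD is over 3 samples, and SE is the log2 fold change divided by the square root of the F statistic. Because the labels do not say that replicates came from separate animals, p values measure the spread between samples.

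Before the data were examined, the contrasts, the tests, 40 gene lists, the first set of alternatives and the rule for naming genes were fixed. The rule took, for each knockout against WT, up to 10 called genes with the largest rise and 10 with the largest fall, given a mean of at least 1 CPM in the higher group and no overlap between the 3 samples of each group. It took 5 and 5 for the other contrasts and skipped predicted genes, Riken clones and pseudogenes. It always took Phlpp1, Phlpp2, Fgf18, Sox9, Col2a1, Acan, Col10a1, Runx2, Ihh, Mmp13 and Pth1r against WT, and from a list 2 to 4 members with the smallest adjusted p and at least 1 CPM on average. Other genes named are said to be chosen after their values were seen.

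The gene lists covered cartilage matrix and chondrocyte identity, signalling, proliferation, stress, metabolism, RNA quality and markers of other cell types. The 36 lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the lists of each contrast. They were tested again with an estimated correlation and with fry, and the values of the other 4 are given without a test. Members passing the gene test were counted over all genes and adjusted over the list alone.

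The gene and list tests were tested on simulated counts with the mean levels, dispersions and scaled library sizes of the real data, with 200 genes changed. For the Phlpp1 knockout against WT (16342 genes), edgeR recovered 14% of 50 genes changed 1.25-fold, 68% at 1.5-fold, 84% at 2-fold and 96% at 4-fold, with 5 false calls among 136. DESeq2 recovered 26%, 80%, 86% and 98%, with 31 false calls among 176. For the interaction (16352 genes), edgeR recovered 2%, 42%, 68% and 96%, with 4 false calls among 108. A simulated list of 25 genes changed 1.25-fold was called by all 3 list tests, which called 0 of 100 unchanged lists. The simulated genes varied independently, so this could not show false list calls that arise where genes vary together.

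Calls were counted within 20 Mb of each targeted gene and compared with all tested genes by Fisher's exact test, two-sided, over 14 tests. Calls shared by knockouts that were compared with the same WT samples were set beside 20 simulations with unchanged groups. The WT counts were simulated there too, with each gene drawn on its own. Near-identical copies of called genes were searched with BLAST+ 2.17.0 among the reference transcripts, taking an identity of at least 95% over at least 150 bases. The search over all called and named genes also dropped matches that covered only a small share of the transcript. A gene given without a copy can thus still hold a short match. Alternatives fixed at that stage were no filter, a CPM of at least 1 in 3 libraries, the size factors of DESeq2, library size alone, DESeq2 1.42.0, limma-voom, a replicate block, a fold threshold of 2, removal of genes near the loci, models of the 6 compared libraries alone, windows of 5 and 40 Mb, and each library left out in turn. Alternatives chosen after seeing the data were protein-coding nuclear genes alone, no genes of the X and Y chromosomes, a targeted gene left out of its own window, the targeted genes left out of their list, and the removal of Phlpp1 KO 1 and Phlpp1/2 KO 1, the pair of libraries with little Xist. Scripts ran in R and Python 3.11.15.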

Results

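RNA was sequenced from epiphyseal chondrocytes of newborn WT mice and of newborn mice labelled as knockouts of Phlpp1, Phlpp2 or both. These genes encode phosphatases that remove phosphate from AKT and other kinases. Each genotype had 3 samples. Library totals were 21706337, 27829144 and 26658108 counts in WT and 30277774, 30415012 and 25555599 in the Phlpp1 knockout. They were 27611205, 30320963 and 26471076 in the Phlpp2 knockout and 30744961, 32727208 and 33115345 in the Phlpp1/2 knockout. The libraries resembled one another closely. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.990 to 0.994 within genotypes (12 pairs) and 0.986 to 0.993 between them (54 pairs). The first principal component carried 18.84% of the variance and the next 15.02%.

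The targeted genes followed the labels for Phlpp1, and for Phlpp2 in part. Phlpp1 (ENSMUSG00000044340, chromosome 1, 106171752 to 106394250, mm10) stood at 39.7 CPM in WT (SD 4.35, range 35.1 to 43.8) and 41.3 CPM in the Phlpp2 knockout (SD 3.33, range 37.9 to 44.6). It fell to 9.16 CPM in the Phlpp1 knockout (SD 0.353, range 8.77 to 9.46) and 8.22 CPM in the Phlpp1/2 knockout (SD 0.568, range 7.71 to 8.83), 4.32-fold and 4.82-fold below WT (adjusted p = 7.11e-08 and 3.45e-08, edgeR's quasi-likelihood test, Benjamini-Hochberg). Phlpp2 (ENSMUSG00000031732, chromosome 8, 109868542 to 109944671) stood at 25.5 CPM in WT (SD 2.85) and 24.2 CPM in the Phlpp1 knockout (SD 1.23). It fell to 10.9 CPM in the Phlpp1/2 knockout (SD 0.611), a log2 fold change of −1.22 (SE 0.10, adjusted p = 2.98e-05). In the Phlpp2 knockout it was 17.8 CPM (SD 1.43, range 16.8 to 19.4), below the WT range of 22.4 to 28.1 but not past the test (log2 fold change −0.52, SE 0.09, adjusted p = 0.0607). Phlpp2 was lower in the Phlpp1/2 knockout than in the Phlpp2 knockout (−0.70, SE 0.10, adjusted p = 0.0185), although both lack Phlpp2 by label. Which part of either gene was removed is not stated in the labels, and the values are sums over the whole gene, so reads outside a removed part would still count.

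**Figure D1:**
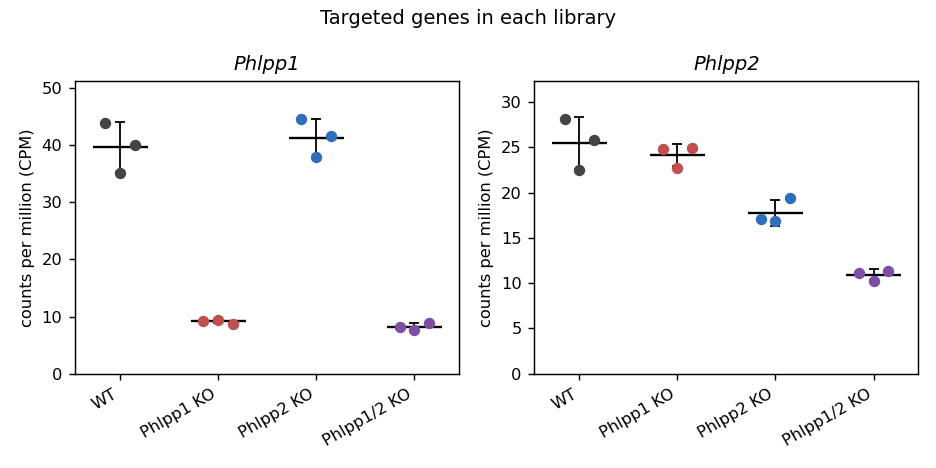
Phlpp1 and Phlpp2 in CPM for each of the 12 libraries, by genotype, with the mean as a line and the SD as a bar (n = 3). Phlpp1 separates the 6 libraries lacking it by label (7.71 to 9.46 CPM) from the other 6 (35.1 to 44.6 CPM), while Phlpp2 is 16.8 to 19.4 CPM in the Phlpp2 knockout and 10.2 to 11.4 CPM in the Phlpp1/2 knockout.

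The labels call every sample female, and 10 libraries had Xist, the RNA that silences 1 X chromosome in female cells, at 278 to 587 CPM. Phlpp1/2 KO 1 had 3.77 CPM of Xist and 108.5 CPM in sum of Ddx3y, Eif2s3y, Uty and Kdm5d, genes of the Y chromosome, against at most 1.23 CPM in any other library. Phlpp1 KO 1 had 13.9 CPM of Xist and 0 counts of those Y genes.

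The cartilage genes taken by the rule, and the lists of cartilage matrix, of hypertrophy and mineralisation and of the articular and superficial zone, gave no call in any knockout against WT. Col2a1, the main collagen of cartilage, was 32927 CPM in WT (SD 7106), 32512 in the Phlpp1 knockout (SD 4922), 29514 in the Phlpp2 knockout (SD 3509) and 27498 in the Phlpp1/2 knockout (SD 6219). Its adjusted p values were 0.968, 0.767 and 0.655. Acan, the main proteoglycan, was 4102, 4325, 3458 and 3647 CPM in the same order (adjusted p = 0.785, 0.433 and 0.667). Sox9, the transcription factor that sets chondrocyte identity, was 382, 319, 333 and 310 CPM (adjusted p = 0.467, 0.686 and 0.583). The list of cartilage matrix genes summed to 49451 CPM in WT (SD 10013), 50688 (SD 8235), 45118 (SD 5689) and 42357 (SD 9068), and its camera test gave adjusted p = 0.738, 0.711 and 0.0699. Among genes of maturing growth plate chondrocytes, Col10a1 was 718, 871, 937 and 567 CPM (adjusted p = 0.617, 0.591 and 0.697), and Ihh was 3.79, 2.28, 3.29 and 2.59 CPM (0.314, 0.837 and 0.620). Mmp13, the collagenase of hypertrophic cartilage, was 186, 119, 226 and 189 CPM (0.147, 0.615 and 0.982). Pth1r, the receptor that holds back hypertrophy, was 54.0, 34.6, 50.4 and 43.4 CPM (0.274, 0.916 and 0.751). Runx2, which drives hypertrophy, was 47.4, 37.8, 46.9 and 39.6 CPM (0.136, 0.964 and 0.408), and Fgf18, a growth factor for chondrocytes, was 1.1004, 1.11, 1.39 and 0.984 CPM (0.999, 0.660 and 0.893). The hypertrophy and mineralisation list gave adjusted p = 0.616, 0.613 and 0.449, and the articular and superficial zone list 0.125, 0.711 and 0.424.

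The comparison of the Phlpp1 knockout with WT asks what loss of this phosphatase alone does to chondrocyte expression. Any other difference between the WT and the knockout samples enters it too, as it does the other comparisons against WT. Among genes that rose were Igfbp3, a carrier of insulin-like growth factors (15.4 to 24.97 CPM, log2 fold change 0.70, SE 0.11), Arc, an immediate early gene (6.88 to 13.4 CPM, 0.97, SE 0.19), and Efcab7, a protein of the primary cilium (3.43 to 6.99 CPM, 1.04, SE 0.19). Mlph, an adaptor for organelle transport, rose from 13.2 CPM (SD 1.84) to 27.9 CPM (SD 0.981; 1.08, SE 0.13). Efhd1, a calcium-binding protein of mitochondria, rose from 0.463 to 1.42 CPM (1.62, SE 0.26). The tRNA methylation factor Trmt11 (0.79), the sialyltransferase St8sia6 (0.71) and the glycan-branching enzyme Gcnt4 (0.61) also rose. Genes that fell included the protease Bace2 (−1.40, SE 0.23), Mcub, which restrains calcium uptake into mitochondria (19.4 to 8.91 CPM, −1.13, SE 0.20), Snapc1, needed for small nuclear RNA transcription (40.8 to 21.2 CPM, −0.95, SE 0.13), Dhrs7, a reductase (38.6 to 20.1 CPM, −0.95, SE 0.10), and Wdfy1, an adaptor of Toll-like receptors (17.6 to 8.86 CPM, −0.99, SE 0.13). Ly6a (−0.98, SE 0.18) and D2hgdh, which breaks down D-2-hydroxyglutarate (−1.10, SE 0.11), fell too, and both share a near-identical stretch with another gene. Every named gene had an adjusted p between 0.000358 and 0.0468 by edgeR's quasi-likelihood test (Benjamini-Hochberg), with all 3 knockout libraries on 1 side of all 3 WT libraries. Efhd1, Mlph and D2hgdh lie within 20 Mb of Phlpp1 on chromosome 1, where calls crowd, and Wdfy1 lies within 40 Mb of it.

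In the interferon response list 19 of 22 genes were lower in the Phlpp1 knockout (median log2 fold change −0.60, camera adjusted p = 1.26e-07; adjusted p = 0.697 with an estimated correlation). Its called members were Irf9, a transcription factor of interferon signalling (−0.63, SE 0.11, adjusted p = 0.0271), and Xaf1, an interferon-induced gene (−1.32, SE 0.25, adjusted p = 0.0323). Adjusted over the list alone, 14 members were lower and 1 higher. In genes chosen after their values were seen, H2-Ab1, a class II antigen-presenting chain (−0.82), the peptide transporter Tap1 (−0.46), the class I chain H2-K1 (−0.47), the signalling adaptor Myd88 (−0.40) and the chemokine Cxcl14 (−0.67) also fell. H2-K1 has near-identical relatives. The inflammatory and NF-kB list was lower as well (22 of 29 genes, camera adjusted p = 0.00575; adjusted p = 0.774 with an estimated correlation), with 0 called members; Lcn2 was −1.63 (SE 0.65, adjusted p = 0.206). That list lost its call without Phlpp1 KO 1 (adjusted p = 0.263) and without both low-Xist libraries (adjusted p = 0.207). Macrophage markers summed to 58.8 CPM (SD 2.85) against 67.5 CPM in WT (SD 3.56). H2-Ab1 was also low in the Phlpp2 knockout (9.51 to 11.4 CPM against 15.4 to 16.9 CPM in WT). There the interferon response list summed to 126 CPM (SD 9.33), against 127 CPM in WT (SD 5.35). The fall of H2-Ab1 thus did not follow the sum of that list.

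Metabolic, proliferation and clock lists moved in the Phlpp1 knockout by small amounts. Of 33 glycolysis and hypoxia genes 32 were lower (median −0.21, camera adjusted p = 1.41e-06; adjusted p = 0.697 with an estimated correlation), led by Pfkfb3, a regulator of glycolytic flux (−0.65, SE 0.16, adjusted p = 0.0858), and the aldolase Aldoc (−0.64, SE 0.18, adjusted p = 0.0980). All 30 cell cycle genes were higher (median 0.17, camera adjusted p = 0.00184; adjusted p = 0.774 with an estimated correlation); Cenpf, a kinetochore protein, was 0.93 (SE 0.26, adjusted p = 0.108). The unfolded protein response list was lower in 19 of 24 genes (median −0.11, 0.00651; adjusted p = 0.697 with an estimated correlation), with Sdf2l1 and Syvn1 at −0.30 and −0.29 (adjusted p = 0.0710 each). The circadian clock list was lower in 16 of 21 genes (median −0.21, 0.00471; adjusted p = 0.697 with an estimated correlation), where the clock output factor Dbp fell (−0.61, SE 0.10, adjusted p = 0.0204), and the list lost its call without Phlpp1 KO 2 (adjusted p = 0.0535). Hedgehog and PTHrP signalling was lower in 14 of 15 genes (median −0.18, 0.00575; adjusted p = 0.697 with an estimated correlation), with Gli1 at −0.90 (SE 0.25, adjusted p = 0.102) and Ptch1 at −0.40 (SE 0.12, adjusted p = 0.108). The list lost its call without WT 3 (adjusted p = 0.0641). Ribosomal protein genes were lower in 41 of 42 (median −0.14, 0.000467; adjusted p = 0.774 with an estimated correlation). This did not hold without WT 2 (adjusted p = 0.294) or Phlpp1 KO 3 (0.0629).

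The last 4 lists passed the camera test in the Phlpp1 knockout, and none of them passed with an estimated correlation (adjusted p = 0.697 each). The FOXO target list was lower in 22 of 28 genes (0.0248), with Txnip, an inhibitor of thioredoxin, at −0.35 (adjusted p = 0.0710). The list lost its call without WT 2 (adjusted p = 0.0755) or Phlpp1 KO 2 (0.174). The list of FGF and ERK feedback targets was higher in 13 of 21 genes (0.0490), with Egr1 at 0.52 (adjusted p = 0.0888) and Dusp6, a phosphatase of ERK, at 0.36 (adjusted p = 0.111), and 3 members passed adjusted over the list alone. That call was lost without WT 2 (0.186), Phlpp1 KO 2 (0.189) or Phlpp1 KO 3 (0.0629). Matrix proteases and inhibitors were lower in 15 of 21 genes (0.0246), with Adamts12 at 0.56 and Mmp19 at −0.69, and lost their call without WT 2 (0.0931), Phlpp1 KO 1 (0.105) or Phlpp1 KO 2 (0.126). Keratinocyte markers were lower in 7 of 7 genes (0.0490) and lost their call without WT 1 (0.0538), WT 2 (0.0616), Phlpp1 KO 2 (0.114) or Phlpp1 KO 3 (0.0851).

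In total 89 of 16565 genes were called between the Phlpp1 knockout and WT, 35 higher and 54 lower, and 3375 had an unadjusted p under 0.05 where chance would give 828. Of the calls 13 were pseudogenes and 23 changed at least 2-fold. In 28.2% of genes the groups did not overlap, where chance gives 10%. DESeq2 called 990 genes (595 higher, 395 lower), among them all 83 of the 89 to which it gave an adjusted p. The count was 461 with no filter (259 higher, 202 lower), 1163 with the 6 compared libraries alone (772 higher, 391 lower) and 72 with limma-voom (28 higher, 44 lower). Which direction had more calls thus depended on the processing. The count fell to 38 without WT 1, 16 without WT 2, 29 without WT 3, 31 without Phlpp1 KO 1, 24 without Phlpp1 KO 2 and 57 without Phlpp1 KO 3, and to 18 without both low-Xist libraries. Phlpp1, Mlph, D2hgdh, Wdfy1 and Dhrs7 were called in 6 of 6 of those refits, Snapc1 in 5, Igfbp3, Bace2, Ly6a and Gcnt4 in 2, Efhd1, Efcab7, Arc, Mcub, Irf9, Dbp and H2-Ab1 in 1, and Xaf1, Trmt11 and St8sia6 in 0.

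**Figure D2:**
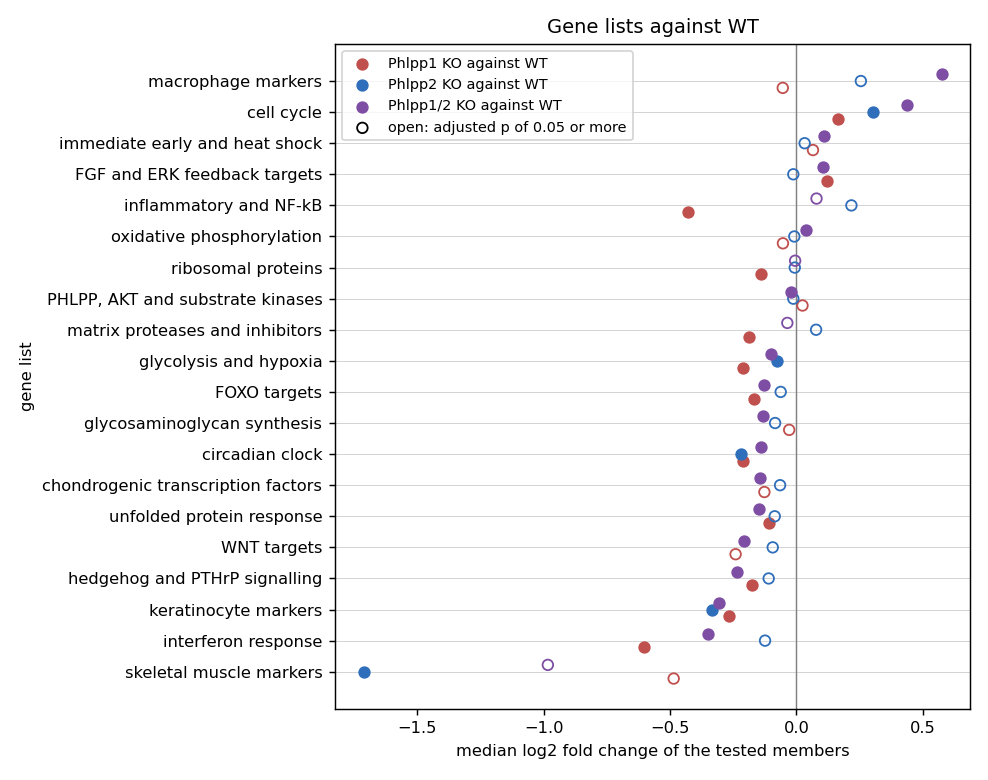
Median log2 fold change of each gene list called in at least 1 knockout against WT, with filled points for a camera adjusted p under 0.05 and open points otherwise. The cell cycle list has medians of 0.17, 0.30 and 0.44 in the Phlpp1, Phlpp2 and Phlpp1/2 knockouts, and the interferon response list is at −0.60 in the Phlpp1 knockout.

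The comparison of the Phlpp2 knockout with WT asks the same of Phlpp2. Sox11, a transcription factor of developing skeletal tissue, rose from 19.3 CPM (SD 3.17) to 30.8 CPM (SD 0.0433; log2 fold change 0.68, SE 0.12, adjusted p = 0.0496). Ska2, a protein of the mitotic spindle, rose from 28.8 to 41.5 CPM (0.53, SE 0.09, adjusted p = 0.0367) but shares 97.6% identity over 328 bases with a pseudogene. Lypd3, a surface glycoprotein, fell from 9.76 CPM (SD 1.02) to 2.45 CPM (SD 0.974; −1.98, SE 0.28, adjusted p = 0.0190). Dbp fell from 25.5 to 16.8 CPM (−0.60, SE 0.10, adjusted p = 0.0496). These values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

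In all, 5 lists passed the camera test in the Phlpp2 knockout. Cell cycle genes were higher in 25 of 30 (median 0.30, adjusted p = 2.17e-05; adjusted p = 0.918 with an estimated correlation), with Cenpf at 1.28 (SE 0.26, adjusted p = 0.144), the checkpoint kinase Bub1 at 0.92 (SE 0.22) and the spindle motor Kif11 at 0.79 (SE 0.20), and 5 members passed adjusted over the list alone. The cell cycle list summed to 3112, 3855 and 4164 CPM in Phlpp2 KO 1, 2 and 3 and 3395, 3303 and 3035 CPM in WT 1, 2 and 3, so that Phlpp2 KO 1 lay within the WT range. The circadian clock list was lower in 15 of 21 genes (median −0.22, 0.000186; adjusted p = 0.632 with an estimated correlation), with the repressor Nr1d1 at −0.45 (SE 0.08, adjusted p = 0.0690) and 7 members lower adjusted over the list alone. Skeletal muscle markers were lower in 13 of 13 genes (median −1.71, 0.000122; adjusted p = 0.918 with an estimated correlation), with the myosin Myh3 at −2.41 (SE 0.75) and the muscle factor Myog at −2.87 (SE 0.90). Their sum was 29.5, 131.8 and 26.5 CPM in WT 1, 2 and 3 and 15.3, 21.2 and 9.85 CPM in the Phlpp2 knockout. Keratinocyte markers were lower in 6 of 7 genes (0.00534; adjusted p = 0.339 with an estimated correlation). The call was lost without Phlpp2 KO 2 (adjusted p = 0.0521). Glycolysis and hypoxia genes were lower in 29 of 33 by a median of −0.08 (0.0390; adjusted p = 0.918 with an estimated correlation). That call ended without WT 2 (adjusted p = 0.235), WT 3 (0.0585), Phlpp2 KO 1 (0.951) or Phlpp2 KO 3 (0.116).

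In total 20 genes were called between the Phlpp2 knockout and WT, 10 higher and 10 lower, of which 11 were pseudogenes. At an unadjusted p under 0.05 there were 2281. DESeq2 called 317 (260 higher, 57 lower), no filter gave 110 (82 higher, 28 lower) and limma-voom 13 (5 higher, 8 lower), so the even balance did not hold in other processing. The count was 9 without WT 2, 12 without WT 3 and 9 without Phlpp2 KO 3. Among protein-coding nuclear genes alone it was 2 (2 higher, 0 lower), and Lypd3 and Dbp were not among them. Their calls thus depended on which genes entered the adjustment. Groups did not overlap in 19.1% of genes, where chance gives 10%. Lypd3 was called in 2 of 6 refits that left out 1 library, and Sox11, Ska2 and Dbp in 1.

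The comparison of the Phlpp1/2 knockout with WT asks what loss of both phosphatases does. Egr1, an immediate early transcription factor, rose from 55.3 CPM (SD 4.93) to 98.0 CPM (SD 15.9; log2 fold change 0.83, SE 0.13, adjusted p = 0.0238), and Fos, a subunit of AP-1, from 13.6 to 20.2 CPM (0.57, SE 0.10, adjusted p = 0.0390). Sox11 rose from 19.3 to 33.4 CPM (0.79, SE 0.12, adjusted p = 0.00901). Tnc, the matrix protein tenascin-C, rose from 372 CPM (SD 49.4) to 546 CPM (SD 7.86; 0.55, SE 0.08, adjusted p = 0.0130). Ciapin1, a factor of iron-sulphur cluster assembly, rose from 67.4 to 114.3 CPM (0.76, SE 0.07, adjusted p = 0.000217); it lies within 20 Mb of Phlpp2. Mlph (0.98, SE 0.13), Efhd1 (1.42, SE 0.26) and the centrosome gene Fgfr1op (0.42, SE 0.07) also rose. H2-Ab1 fell from 16.1 CPM (SD 0.793) to 8.63 CPM (SD 1.08; −0.90, SE 0.14, adjusted p = 0.0139). Wdfy1 (−1.09, SE 0.13), D2hgdh (−1.06, SE 0.11), Asb16 (−1.21, SE 0.22) and Ggn (−0.86, SE 0.16) fell, as did Mid1, a ubiquitin ligase on microtubules with a near-identical pseudogene (−0.97, SE 0.18).

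Of the lists, 16 passed the camera test in the Phlpp1/2 knockout and 6 of these also passed fry. Immediate early and heat shock genes were higher in 22 of 26 (median 0.11, adjusted p = 5.42e-06; adjusted p = 0.0896 with an estimated correlation; fry 0.0181), with Egr1 and Fos called and 9 members higher adjusted over the list alone. FGF and ERK feedback targets were higher in 15 of 21 (median 0.10, 0.000305; adjusted p = 0.229 with an estimated correlation), with Dusp6 at 0.39 (SE 0.11) and Spry4, a brake on receptor signalling, at 0.31 (SE 0.09). Cell cycle genes were higher in 29 of 30 (median 0.44, 1.47e-12; adjusted p = 0.229 with an estimated correlation), with Bub1 at 0.74 (SE 0.22, adjusted p = 0.281) and Cenpf at 0.85 (SE 0.26, adjusted p = 0.295). The unfolded protein response list was lower in 22 of 24 (median −0.15, 7.32e-07; adjusted p = 0.0896 with an estimated correlation; fry 0.0181), with the chaperone Hspa5 at −0.21 (SE 0.06). The list of PHLPP, AKT and substrate kinases was lower in 18 of 29 (median −0.02, 2.33e-05; adjusted p = 0.0896 with an estimated correlation; fry 0.0181) with both targeted genes among its members and Foxo1 and Foxo3 each at −0.25 (SE 0.07). Without the targeted genes that list had an adjusted p = 0.448, and its call rests on them. FOXO targets were lower in 21 of 28 (median −0.13, 0.00219; adjusted p = 0.2501 with an estimated correlation), and Txnip fell (−0.45, SE 0.08, adjusted p = 0.0355). WNT targets were lower in 18 of 21 (median −0.21, 0.00290; adjusted p = 0.0896 with an estimated correlation; fry 0.0181), with the receptor Lgr6 at −0.41 (SE 0.11) and the ligand Wnt5b at −0.34 (SE 0.10). The circadian clock list was lower in 17 of 21 (median −0.14, 2.33e-05; adjusted p = 0.160 with an estimated correlation; fry 0.0321), where Dbp fell (−0.73, SE 0.10, adjusted p = 0.00851) and Nr1d1 was −0.41 (adjusted p = 0.0904).

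The lists of matrix polysaccharide synthesis and of cartilage transcription were lower in the Phlpp1/2 knockout by the preset camera test. Neither passed with an estimated correlation. In the glycosaminoglycan synthesis list 22 of 25 genes were lower (median −0.13, 0.000305; adjusted p = 0.229 with an estimated correlation), with the chondroitin polymerase Chpf2 at −0.21 (SE 0.05, adjusted p = 0.171) and the hyaluronan synthase Has2 at −0.42 (SE 0.12, adjusted p = 0.231). The chondrogenic transcription factor list was lower in 15 of 18 (median −0.14, 0.0164; adjusted p = 0.557 with an estimated correlation), with Runx3 and Runx2 each at −0.26. The list lost its call without WT 3 (adjusted p = 0.132) or Phlpp1/2 KO 3 (0.0758). Hedgehog and PTHrP signalling was lower in 13 of 15 (0.00219; adjusted p = 0.365 with an estimated correlation). This did not hold without WT 3 (adjusted p = 0.0504) or Phlpp1/2 KO 3 (0.0699). The interferon response list was lower in 19 of 22 (median −0.35, 0.000135; adjusted p = 0.365 with an estimated correlation), with Xaf1 at −1.01 (SE 0.23, adjusted p = 0.150). Glycolysis and hypoxia genes were lower in 27 of 33 (0.00863; adjusted p = 0.698 with an estimated correlation). The call was lost without WT 2 (adjusted p = 0.154). Oxidative phosphorylation genes were higher in 26 of 30 by a median of 0.04 (0.0424; adjusted p = 0.698 with an estimated correlation). That call ended without WT 1 (adjusted p = 0.246), WT 3 (0.532), Phlpp1/2 KO 1 (0.125), Phlpp1/2 KO 2 (0.360) or both low-Xist libraries (0.0906). Macrophage markers were higher in 12 of 14 (median 0.57, 0.00174; adjusted p = 0.229 with an estimated correlation), with Mrc1 at 0.68 (SE 0.29, adjusted p = 0.418) and a sum of 73.4 CPM (SD 10.8). Keratinocyte markers were lower in 7 of 7 (0.00219; adjusted p = 0.0896 with an estimated correlation; fry 0.0181), and their sum was 57.8 CPM against 75.1 CPM in WT.

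In total 39 genes were called between the Phlpp1/2 knockout and WT, 17 higher and 22 lower, with 1836 at an unadjusted p under 0.05. DESeq2 called 168 (75 higher, 93 lower). The count was 23 without WT 1, 21 without WT 2, 18 without WT 3, 23 without Phlpp1/2 KO 1 and 21 without Phlpp1/2 KO 2. Phlpp1, Phlpp2, Mlph, D2hgdh, Wdfy1 and Ciapin1 were called in 6 of 6 of those refits, Sox11 and Dbp in 3, Tnc in 2, Egr1, Fos, Asb16 and H2-Ab1 in 1, and Efhd1, Mid1, Ggn and Fgfr1op in 0. Groups did not overlap in 18.9% of genes, where chance gives 10%.

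**Figure D3:**
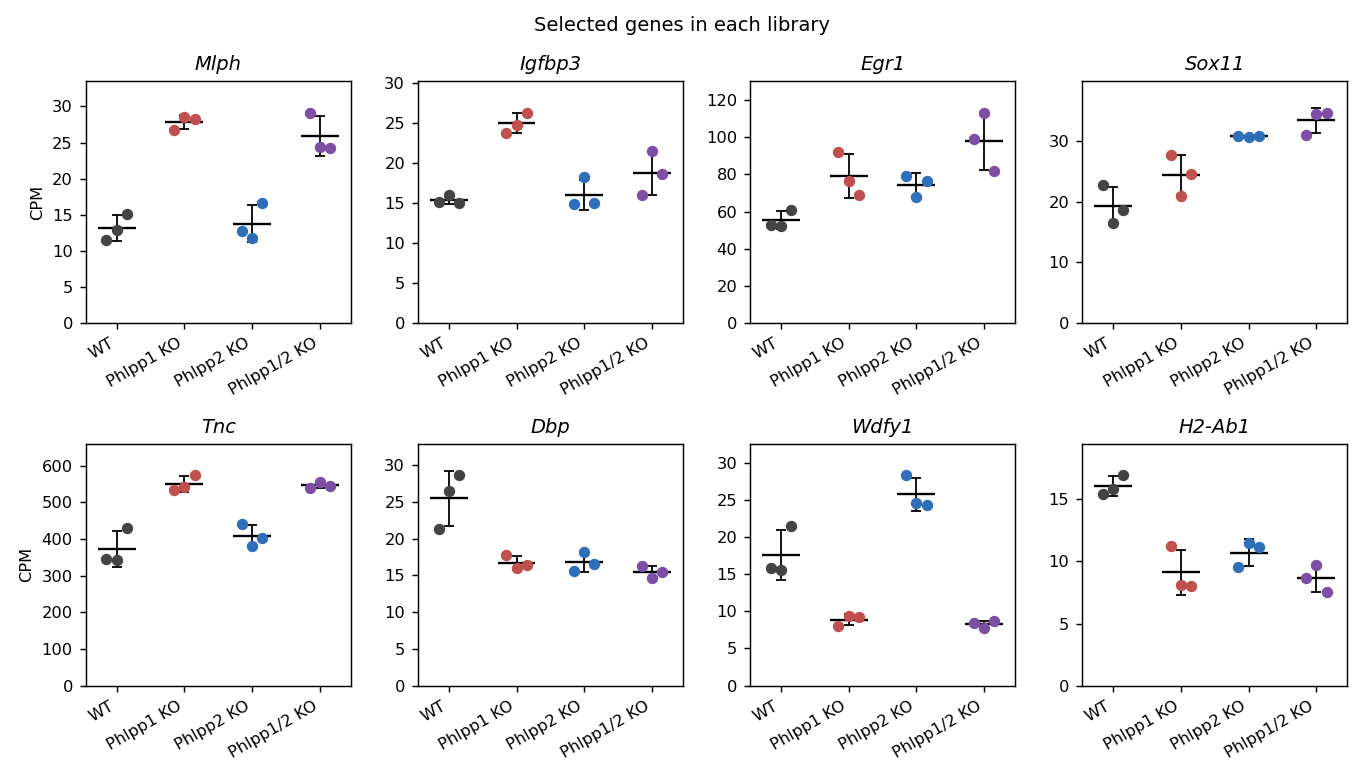
CPM of Mlph, Igfbp3, Egr1, Sox11, Tnc, Dbp, Wdfy1 and H2-Ab1 in each of the 12 libraries by genotype, with the mean as a line and the SD as a bar (n = 3). Egr1 is 52.0 to 61.0 CPM in WT and 81.6 to 113.3 CPM in the Phlpp1/2 knockout, and Dbp is lower in all 9 knockout libraries than in any WT library.

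Between the Phlpp1/2 and Phlpp1 knockouts, which differ by label in Phlpp2, 2 genes were called by edgeR's quasi-likelihood test (Benjamini-Hochberg): Phlpp2, which fell (−1.15, SE 0.10, adjusted p = 0.000304), and Ciapin1, which rose from 71.0 to 114.3 CPM (0.69, SE 0.07, adjusted p = 0.00280). Both lie within 20 Mb of Phlpp2, and both were called in 6 of 6 refits that left out 1 library. The count at an unadjusted p under 0.05 was 1308, DESeq2 called 21, and 4 genes were called without Phlpp1 KO 2. Macrophage markers were higher in 14 of 14 genes (median 0.43, camera adjusted p = 1.91e-06; adjusted p = 0.432 with an estimated correlation), with Laptm5 at 0.43 (SE 0.17, adjusted p = 0.625). Inflammatory and NF-kB genes were higher in 27 of 29 (median 0.54, 8.82e-07; adjusted p = 0.798 with an estimated correlation), with the chemokine Ccl5 at 0.79 (SE 0.26). Ribosomal protein genes were higher in 42 of 42 (median 0.13, 6.54e-09), oxidative phosphorylation genes in 28 of 30 (0.09, 0.000143) and glycolysis and hypoxia genes in 27 of 33 (0.12, 0.000277), each with an adjusted p = 0.798 with an estimated correlation. Glycosaminoglycan synthesis was lower in 19 of 25 genes (median −0.14, 0.00168; adjusted p = 0.722 with an estimated correlation), with Has2 at −0.40 (SE 0.12), and the list of PHLPP, AKT and substrate kinases was lower in 21 of 29 (0.000829; adjusted p = 0.512 with an estimated correlation; adjusted p = 0.0786 without the targeted genes).

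Another 5 lists passed between the Phlpp1/2 and Phlpp1 knockouts and lost the call when 1 library was left out. Cartilage matrix genes were lower in 18 of 22 (median −0.26, 0.00898; adjusted p = 0.798 with an estimated correlation), with the link protein Hapln1 at −0.35 (SE 0.14) and Acan at −0.25 (SE 0.13). That list lost the call without Phlpp1 KO 1 (adjusted p = 0.781), Phlpp1/2 KO 3 (0.946) or both low-Xist libraries (0.534). Matrix proteases and inhibitors were higher in 16 of 21 (median 0.19, 0.00278; adjusted p = 0.722 with an estimated correlation), with Mmp13 at 0.67 (SE 0.22) and Mmp2 at 0.25 (SE 0.08), and lost it without Phlpp1 KO 1 (0.0669) or Phlpp1 KO 2 (0.103). Interferon response genes were higher in 19 of 22 (0.00168; adjusted p = 0.798 with an estimated correlation) and lost it without Phlpp1 KO 1 (0.0790) or Phlpp1/2 KO 3 (0.171). Cell cycle genes were higher in 24 of 30 (0.00207; adjusted p = 0.798 with an estimated correlation) and lost it without Phlpp1 KO 2 (0.0681) or Phlpp1/2 KO 3 (0.0599). Immediate early and heat shock genes were higher in 22 of 26 (0.0124; adjusted p = 0.722 with an estimated correlation) and lost it without Phlpp1 KO 1 (0.0986), Phlpp1/2 KO 2 (0.114) or both low-Xist libraries (0.0761).

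Between the Phlpp1/2 and Phlpp2 knockouts, which differ by label in Phlpp1, 12 genes were called, 6 higher and 6 lower. Fosb, another AP-1 subunit, rose from 2.82 to 4.92 CPM (0.80, SE 0.13, adjusted p = 0.0469), the stress-induced Zfand2a from 73.1 to 97.5 CPM (0.42, SE 0.07, adjusted p = 0.0432), and Ciapin1 from 83.2 to 114.3 CPM (0.46, SE 0.07, adjusted p = 0.0439). Mlph rose (0.92, SE 0.13), as did Dgkd, a diacylglycerol kinase (0.35, SE 0.06). Phlpp1 fell (−2.33, adjusted p = 4.83e-08), and so did Wdfy1 (25.7 to 8.29 CPM, −1.63, SE 0.13), D2hgdh (−0.95, SE 0.11), Phlpp2 and Pign, a gene of lipid anchor synthesis that matches part of Thada (−0.60, SE 0.09). By edgeR, 1465 genes had an unadjusted p under 0.05, and DESeq2 called 44. The count was 5 without Phlpp2 KO 2 (0 higher, 5 lower), 5 without Phlpp2 KO 3 and 4 without Phlpp1/2 KO 1. It was 132 without Phlpp1/2 KO 3 (18 higher, 114 lower) and 3 without both low-Xist libraries. The even balance thus depended on single libraries. Phlpp1, Wdfy1 and D2hgdh were called in 6 of 6 of those refits that left out 1 library, Mlph and Phlpp2 in 3, Dgkd in 2, and Ciapin1, Fosb, Zfand2a and Pign in 1.

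Lists that kept their call in every such refit between the Phlpp1/2 and Phlpp2 knockouts were FGF and ERK feedback targets, higher in 15 of 21 genes (median 0.13, camera adjusted p = 0.00116; adjusted p = 0.430 with an estimated correlation), and mitochondrially encoded genes, lower in 10 of 13 (median −0.26, 0.00116; adjusted p = 0.582 with an estimated correlation). The list of PHLPP, AKT and substrate kinases also passed (lower in 18 of 29, median −0.02, 9.29e-05; adjusted p = 0.385 with an estimated correlation), but holds Phlpp1 and Phlpp2, and without them its adjusted p was 0.418. Among the FGF and ERK targets Spry4 was 0.32 (SE 0.09) and Egr1 0.40 (SE 0.13). ATF4 and amino acid synthesis genes were higher in 21 of 25 (median 0.18, 0.000528; adjusted p = 0.739 with an estimated correlation), with the serine synthesis enzyme Phgdh at 0.34 (SE 0.06, adjusted p = 0.0869). That list lost the call without Phlpp1/2 KO 2 (adjusted p = 0.242). Glycosaminoglycan synthesis was lower in 19 of 25 (0.00732; adjusted p = 0.582 with an estimated correlation), with Has2 at −0.67 (SE 0.12, adjusted p = 0.0869). That list lost the call without Phlpp2 KO 2 (0.142) or Phlpp2 KO 3 (0.0962). Osteoblast genes were lower in 7 of 8 (median −0.34, 0.00648; adjusted p = 0.385 with an estimated correlation), with Omd, a matrix protein of bone, at −1.15 (SE 0.34). That list lost the call without Phlpp2 KO 3 (0.0518) or Phlpp1/2 KO 3 (0.138). The unfolded protein response list was lower in 18 of 24 (0.00388; adjusted p = 0.492 with an estimated correlation) and lost it without Phlpp2 KO 3 (0.0518) or Phlpp1/2 KO 3 (0.108). Immediate early and heat shock genes were higher in 21 of 26 (0.00116; adjusted p = 0.385 with an estimated correlation) and lost it without Phlpp2 KO 3 (0.0518). Skeletal muscle markers were higher in 13 of 13 (median 0.65, 0.00736; adjusted p = 0.739 with an estimated correlation) and lost it without Phlpp2 KO 3 (0.128) or Phlpp1/2 KO 3 (0.224). Interferon response genes were lower in 19 of 22 (0.0191; adjusted p = 0.739 with an estimated correlation) and lost it without Phlpp2 KO 2 (0.334), Phlpp1/2 KO 2 (0.138) or both low-Xist libraries (0.0567). Cell cycle (22 of 30, adjusted p = 0.0373; 0.863 with an estimated correlation), oxidative phosphorylation (23 of 30, 0.0402; 0.863) and macrophage genes (10 of 14, 0.0425; 0.586) were higher, and each lost its call without at least 3 of the 6 libraries in turn.

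Between the Phlpp1 and Phlpp2 knockouts 25 genes were called, 12 higher and 13 lower in the Phlpp1 knockout. Sema3e, a guidance cue that repels vessels, was higher in the Phlpp1 knockout (142 against 104 CPM, 0.46, SE 0.07, adjusted p = 0.0237), with Igfbp3 (0.64, SE 0.11, adjusted p = 0.0415), Mlph (1.02, SE 0.13), Efhd1 (1.57, SE 0.26) and Spns2, a transporter of sphingosine-1-phosphate (12.5 against 7.38 CPM, 0.76, SE 0.11). Lower were Phlpp1 (−2.17), Angptl7, a secreted glycoprotein (3.51 against 7.45 CPM, −1.09, SE 0.18), Snapc1 (21.2 against 48.3 CPM, −1.19, SE 0.13), Wdfy1 (−1.54, SE 0.13) and Cntnap1 (−1.70, SE 0.23). By edgeR's quasi-likelihood test (Benjamini-Hochberg) 1730 genes had an unadjusted p under 0.05, and DESeq2 called 176 genes. The count was 13 without Phlpp1 KO 1, 8 without Phlpp1 KO 2, 38 without Phlpp1 KO 3, 207 without Phlpp2 KO 1, 11 without Phlpp2 KO 2 and 13 without Phlpp2 KO 3, and 11 without both low-Xist libraries. Phlpp1, Wdfy1 and Snapc1 were called in 6 of 6 of those refits, Mlph and Cntnap1 in 5, Spns2 and Sema3e in 3, Igfbp3 in 2, and Efhd1 and Angptl7 in 1.

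Lists of inflammation and of matrix breakdown were lower in the Phlpp1 than in the Phlpp2 knockout, and held in all 6 refits. Inflammatory and NF-kB genes were lower in 26 of 29 (median −0.71, camera adjusted p = 5.27e-09; adjusted p = 0.757 with an estimated correlation), with Ccl5 at −1.15 (SE 0.26, adjusted p = 0.138) and the cytokine Il6 at −2.77 (SE 0.91). Interferon response genes were lower in 22 of 22 (median −0.44, 1.22e-07; adjusted p = 0.633 with an estimated correlation), with Irf9 at −0.36 (SE 0.11). Matrix proteases and inhibitors were lower in 19 of 21 (median −0.21, 1.13e-05; adjusted p = 0.633 with an estimated correlation), with Mmp13 at −0.92 (SE 0.22, adjusted p = 0.182) and 6 members lower adjusted over the list alone. Ribosomal protein genes were lower in 42 of 42 (median −0.12, 3.55e-07) and skeletal muscle markers higher in 13 of 13 (median 1.17, 0.000110), each with an adjusted p = 0.757 with an estimated correlation. Osteoblast genes were lower in 7 of 8 (0.0150; adjusted p = 0.633 with an estimated correlation), with Omd at −0.75 (SE 0.33) and the bone transcription factor Sp7 at −0.48 (SE 0.25). That list lost the call without Phlpp2 KO 3 (adjusted p = 0.0679). Glycolysis and hypoxia genes were lower in 27 of 33 (0.00101; adjusted p = 0.757 with an estimated correlation) and lost it, with the direction turned, without Phlpp2 KO 2 (0.959). ATF4 and amino acid synthesis genes were higher in 22 of 25 (0.00667; adjusted p = 0.757 with an estimated correlation) and lost it without Phlpp1 KO 1 (0.919). Mitochondrially encoded genes (lower in 13 of 13, 0.0347), FGF and ERK feedback targets (higher in 16 of 21, 0.0431), macrophage markers (lower in 12 of 14, 0.0431) and endothelial markers (lower in 11 of 13, 0.0431) had an adjusted p = 0.757 with an estimated correlation, and each lost its call without at least 3 of the 6 libraries in turn.

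The interaction asks whether both losses add up. Of 8 genes called, mt-Nd3 was the one with a standard symbol (3.93, SE 0.26) and the other 7 were pseudogenes, so no protein-coding nuclear gene was called by edgeR, which found 2410 genes at an unadjusted p under 0.05. Against WT, mt-Nd3 fell alike in every knockout (−3.65, −3.59 and −3.31), which by itself gives an interaction. DESeq2 called 650 (40 higher, 610 lower). The count was 5 without WT 3, Phlpp1 KO 3, Phlpp2 KO 1, Phlpp2 KO 3 or Phlpp1/2 KO 1, 71 without Phlpp2 KO 2, 1196 without Phlpp1/2 KO 3 and 4 without both low-Xist libraries. Glycolysis and hypoxia genes lay above the sum of the single losses in 31 of 33 (median 0.21, camera adjusted p = 0.000538; adjusted p = 0.919 with an estimated correlation). Ribosomal protein genes did so in 38 of 42 (0.00856; adjusted p = 0.919 with an estimated correlation). This did not hold without WT 2 (adjusted p = 0.544), Phlpp1 KO 3 (0.144) or Phlpp2 KO 3 (0.139). Interferon response genes did so in 18 of 22 (median 0.42, 0.0202; adjusted p = 0.919 with an estimated correlation), with Irf9 at 0.53 (SE 0.16, adjusted p = 0.155). The call was lost without WT 2 (0.0625), Phlpp1 KO 1 (0.0921), Phlpp2 KO 1 (0.0734), Phlpp2 KO 3 (0.0504) or Phlpp1/2 KO 3 (0.128).

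Calls crowded around Phlpp1 on chromosome 1. In the Phlpp1 knockout against WT, 8 of 88 positioned calls lay within 20 Mb of Phlpp1, where 0.890% of 16524 tested genes lie (odds ratio 11.7, Fisher's exact test, two-sided, p = 1.14e-06, adjusted p = 5.32e-06). In the Phlpp1/2 knockout against the Phlpp2 knockout it was 7 of 12 calls (odds ratio 162.5, exact adjusted p = 4.07e-11), in the Phlpp1/2 knockout against WT 5 of 39 (16.9, exact adjusted p = 8.22e-05) and between the single knockouts 7 of 25 (45.3, exact adjusted p = 1.13e-08). Phlpp1 itself is 1 of these calls each time. Without it 7 of 87 (odds ratio 10.25), 6 of 11 (139.7), 4 of 38 (13.53) and 6 of 24 (38.88) remained, in the same order. Their unadjusted exact p was at most 0.000342. Mlph (90915085 to 90951142), Efhd1 (87264363 to 87310839), Dgkd (87853287 to 87945180), D2hgdh (93824909 to 93852348) and Pign (105518422 to 105663677) lie in this window. Wdfy1 (79702262 to 79776143) lies outside it but inside a window of 40 Mb. That wider window held 9 of 88 calls of the Phlpp1 knockout against WT (odds ratio 4.74) and 6 of 39 of the Phlpp1/2 knockout against WT (7.52). It held 8 of 12 for the Phlpp1/2 against the Phlpp2 knockout (83.2) and 8 of 25 between the single knockouts (19.6). Each had an unadjusted exact p of at most 0.000301. Without Phlpp1 itself the wider window held 8 of 87 (odds ratio 4.21), 5 of 38 (6.268), 7 of 11 (72.72) and 7 of 24 (17.13). Their unadjusted exact p was at most 0.00197. Around Phlpp2 on chromosome 8, 3 of 39 calls of the Phlpp1/2 knockout against WT (Phlpp2, Ciapin1 and Ndrg4) were found within 20 Mb (odds ratio 3.93, exact adjusted p = 0.0948) and 1 of 20 of the Phlpp2 knockout (2.47, exact adjusted p = 0.602). Both of the 2 calls of the Phlpp1/2 against the Phlpp1 knockout lay there (exact adjusted p = 0.00122), and 2 of 12 against the Phlpp2 knockout (9.42, exact adjusted p = 0.0583). In each, 1 of these calls is Phlpp2 itself; without it 1 of 1 (unadjusted exact p = 0.0208) and 1 of 11 (4.71, unadjusted exact p = 0.207) remained.

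**Figure D4:**
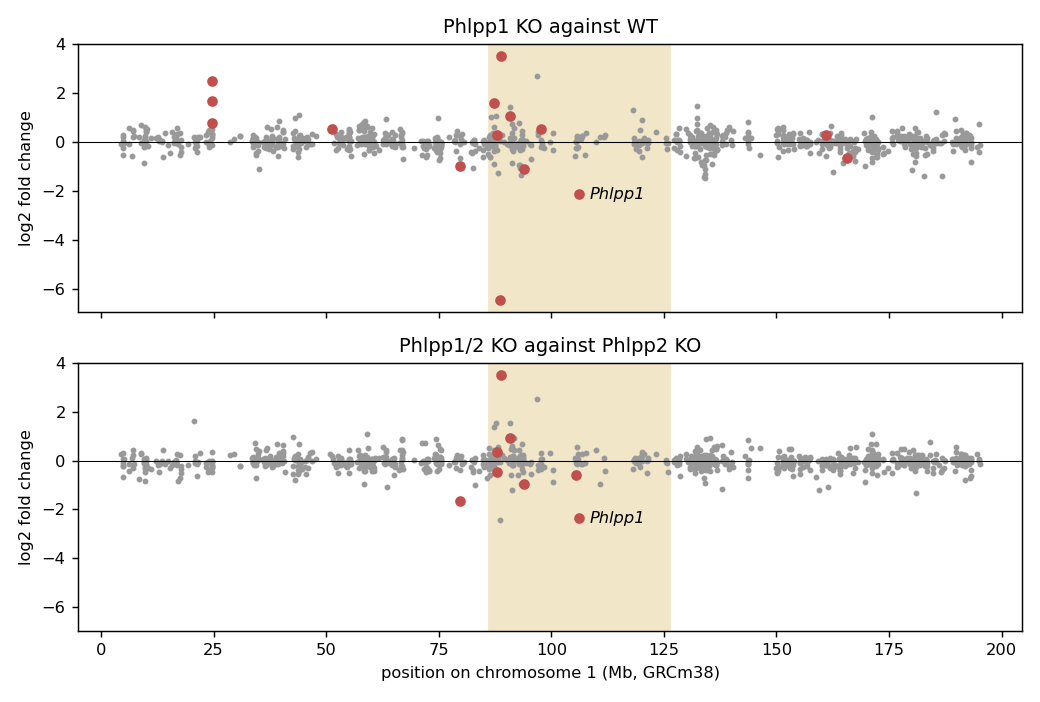
Log2 fold change of tested genes by position on chromosome 1 in the Phlpp1 knockout against WT and the Phlpp1/2 knockout against the Phlpp2 knockout, with called genes in red and the 20 Mb on either side of Phlpp1 shaded. The shaded part holds 8 and 7 of the called genes, Phlpp1 itself among them each time.

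The knockouts shared calls against WT. The Phlpp1 and Phlpp1/2 knockouts shared 26 genes in the same direction, the Phlpp1 and Phlpp2 knockouts 15, and the Phlpp2 and Phlpp1/2 knockouts 13. In 20 simulations of unchanged groups they shared at most 0, 0 and 1. With no gene changed, few calls can arise there, so these counts do not show what changed groups would share by chance. If the real calls were independent, they would share 0.0359 higher and 0.0717 lower genes, 0.0211 and 0.0326, and 0.0103 and 0.0133. Those values leave the shared WT samples out of account. Those simulations also drew the shared WT counts anew, and drew each gene on its own. They thus keep neither the real WT counts nor any correlation between genes. The covariance of log2 fold changes across genes was 0.0708, 0.0614 and 0.0649, against simulated means of 0.0317, 0.0316 and 0.0316. Their Pearson correlation was 0.670, 0.536 and 0.643, against simulated means of 0.527, 0.517 and 0.526. The highest simulated correlations were 0.549, 0.540 and 0.557. By correlation, the Phlpp1 and Phlpp2 knockouts thus lay within the simulated range. All knockouts were compared with the same 3 WT samples, which are too few to give each knockout its own, so part of the excess is open to chance differences in those samples. Of 12 genes called in all 3 knockouts 11 have a near-identical copy elsewhere in the genome, and the other was Dbp, which overlaps Sphk2 on the opposite strand over 18.0% of its exons. Rps2-ps10, a processed copy of the ribosomal protein gene Rps2 (99.4% identity over 934 bases), fell from 544 CPM in WT to 18.7, 17.7 and 18.4 CPM, while Rps2 rose from 1670 to 2678 CPM in the Phlpp1 knockout (0.68, 0.69 and 0.78 in the 3 knockouts). The mitochondrial gene mt-Nd3, a subunit of respiratory complex I, fell from 19.7 to 1.56, 1.63 and 1.98 CPM, while its nuclear copy Gm28438 (99.7% identity over 345 bases) rose from 2.68 to 15.3, 21.1 and 17.4 CPM. Rnps1, a splicing factor, rose by 0.46, 0.37 and 0.41 while its copy Gm9825 fell by 2.97, 3.00 and 2.84 on the log2 scale. In the Phlpp1/2 knockout mt-Nd4l, identical to its nuclear copy Gm10222 over 294 bases, fell too (−1.14, SE 0.19). Values of these genes are uncertain, since near-identical copies can take each other's reads.

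**Figure D5:**
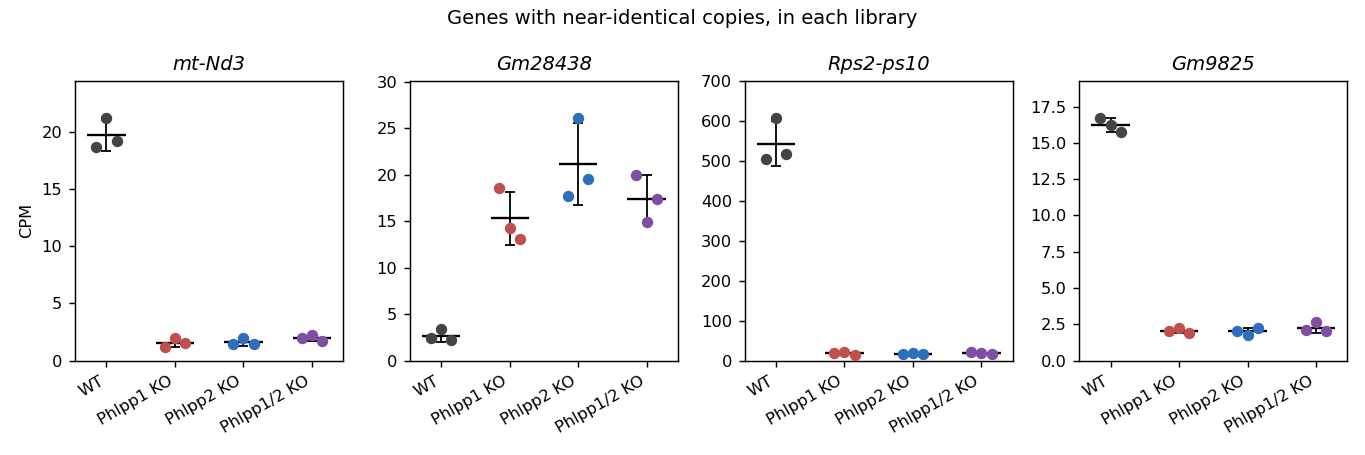
CPM of mt-Nd3, Gm28438, Rps2-ps10 and Gm9825 in each of the 12 libraries by genotype, with the mean as a line and the SD as a bar (n = 3). Rps2-ps10 averages 544 CPM in WT and at most 18.7 CPM in a knockout group, and Gm28438 is higher in all 9 knockout libraries than in WT.

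Overlaps were searched for called genes and for those taken by the rule, and several overlap a gene with a mean of at least 1 CPM on the opposite strand, where strand use is not stated. Besides Dbp, those named here are Myd88 with Acaa1a (11.3% of its exons), Ggn with Spred3 (7.21%), Runx2 with Runx2os1 (5.87%), Cntnap1 with Plekhh3 (3.97%), Spns2 with Mybbp1a (3.21%), Wdfy1 with Mrpl44 (1.94%), Dgkd with Usp40 (0.905%), Col10a1 with Nt5dc1 (0.575%) and Ciapin1 with Coq9 (0.413%). Irf9 overlaps Rnf31 on the same strand (2.28%).

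Other lists gave no call in any knockout against WT by camera. In the order Phlpp1, Phlpp2 and Phlpp1/2 knockout, adjusted p values were 0.269, 0.126 and 0.201 for fibroblast and dedifferentiation genes, 0.499, 0.297 and 0.237 for osteoblast genes, 0.524, 0.852 and 0.120 for FGF ligands and receptors, 0.204, 0.126 and 0.341 for sterol and fatty acid synthesis, 0.487, 0.229 and 0.0795 for ATF4 and amino acid synthesis, and 0.824, 0.779 and 0.428 for TGF-beta and BMP targets. Osteoblast genes summed to 210 CPM in WT (SD 49.6), 141 (SD 22.6), 214 (SD 51.4) and 131 (SD 41.5). Mitochondrially encoded genes gave adjusted p = 0.604, 0.308 and 0.0699; camera placed them lower in the Phlpp1 and Phlpp1/2 knockouts and higher in the Phlpp2 knockout, although 10 of 13 were higher in each, with medians of 0.29, 0.49 and 0.22. Its member mt-Nd3 had log2 fold changes of −3.65, −3.59 and −3.31. Their share of counts was 0.674 to 0.751% in WT, 0.842 to 1.1% in the Phlpp1 knockout, 0.911 to 1.14% in the Phlpp2 knockout and 0.749 to 1.05% in the Phlpp1/2 knockout. Osteoclast (131, 132, 136 and 139 CPM in WT and the knockouts), endothelial (17.8, 18.3, 21.3 and 20.4), mural (534, 502, 468 and 466), adipocyte (52.0, 52.0, 52.9 and 58.1), Schwann cell and neuron (40.7, 39.0, 39.9 and 35.5) and tendon markers (812, 799.8, 873 and 805) were not called against WT either. Lists too small to test summed to 1.43, 1.66, 1.34 and 1.46 CPM for granulocytes, 24.9, 21.6, 26.9 and 25.1 CPM for lymphocytes and 67.1, 66.9, 66.4 and 72.2 CPM for erythroid cells.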

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

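The counts of other splits of the samples were planned, and the tests of copies, of chromosome 1 and of the sex chromosomes were chosen only after the results were seen.

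The interaction of both losses, which compares the effect of Phlpp2 loss with and without Phlpp1, called 8 genes. On the log2 scale these were Gm10222 (−1.73), Gm28438 (−2.78), Gm28437 (−0.93), Rps2-ps13 (1.23), Gm6139 (2.57), Gm9825 (3.13), Rps2-ps10 (4.91) and mt-Nd3 (3.93). All but Rps2-ps13 were called in the same direction in all 3 knockouts against WT. Rps2-ps10, for example, was at −4.86, −4.94 and −4.89. Such a shift shared by all knockouts by itself gives an interaction, so these calls need not mean that the effect of Phlpp2 loss depends on Phlpp1. The interferon response (adjusted p = 0.0202), glycolysis and hypoxia (adjusted p = 0.000538) and ribosomal protein lists (adjusted p = 0.00856) passed in the preset camera test, but none of the 3 with an estimated correlation (adjusted p = 0.919 each). The ribosomal call was lost without WT 2 (0.544), Phlpp1 KO 3 (0.144) or Phlpp2 KO 3 (0.139). Of 100 splits of the 12 libraries, 4 called at least 8 genes with the real one included. These splits also mix the effects of the single losses into the spread within groups, so they say nothing on chance for the interaction alone. The highest other split called 667, which points to a structure of the samples, which can be genotype itself. Leaving out WT 2, Phlpp1 KO 1, Phlpp2 KO 1, Phlpp2 KO 3 or Phlpp1/2 KO 3 ended the interferon call, as given with the interaction.

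For each pair of groups the 6 libraries allow 10 splits, too few for a share under 0.05. With the real split included, 1 split called as many genes for each knockout against WT: the Phlpp1 knockout had 89 with 0 as the highest other, the Phlpp2 knockout 20 with 0, and the Phlpp1/2 knockout 39 with 2. Between knockouts 2 splits did so each time. The Phlpp1/2 knockout had 2 calls against the Phlpp1 knockout with 5 as the highest other and 12 against the Phlpp2 knockout with 396, and the single knockouts had 25 with 35. The split with 396 calls set Phlpp2 KO 1, Phlpp2 KO 3 and Phlpp1/2 KO 3 against the other 3 libraries, and points to a structure of the samples that does not follow genotype.

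The first pattern is that genes with near-identical copies separate WT from every knockout library. All knockouts moved together in these genes, which by itself gives an interaction. A sequence difference between WT and knockout mice that moves reads between copies is a candidate explanation: the knockouts' summed CPM differed from WT by −0.19 for mt-Nd3 with Gm28438, 0.32 for Rps2 with its 4 called copies and 0.23 for Rnps1 with Gm9825 on the log2 scale, while single members moved by −3.52, −4.89 and −2.94. A read length or mapping setting that differed between WT and knockout libraries stays open: 7 of 642 tested pseudogenes with at least 1 CPM on average (1.09%) were called in all 3 comparisons, and how many copies such a setting would move is not known. The sums still rose without overlap between WT and knockout libraries for Rps2 (2084 to 2439 against 2527 to 3013 CPM) and Rnps1 (126 to 128 against 142 to 161 CPM). These rises, and a response to Phlpp loss, stay open too. Whatever set the WT samples apart from all knockouts also enters every comparison against WT and the interaction. There it cannot be told apart from Phlpp loss.

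The next pattern is the crowding of calls around Phlpp1. A response of genes anywhere in the genome is argued against as its whole cause, since without Phlpp1 itself the lower 95% limit of the odds ratio in the Phlpp1 knockout against WT was 3.92. DNA flanking the targeted allele from another mouse strain is a candidate explanation: in the Phlpp1/2 against the Phlpp2 knockout, which shares no library with that comparison, the odds ratio without Phlpp1 was 139.7. There 7 of 7 of the nearby genes changed in the same direction and 4 were called again, against 57 of 81 and 1 for calls elsewhere. This pair also differs in Phlpp1 by label. A response of these genes to Phlpp1 loss predicts the same, so the repeat does not favour flanking DNA over it. An effect of the altered locus on its neighbours stays open. Mlph, Efhd1 and D2hgdh, and Wdfy1 farther off on the same chromosome, may therefore differ for reasons other than the lost phosphatase.

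The last pattern is the sex chromosome levels of the libraries Phlpp1/2 KO 1 and Phlpp1 KO 1, a signal outside the comparisons. In Phlpp1/2 KO 1 the 4 Y genes summed to 108.5 CPM, 88.6 times the highest of the other 11 libraries, and a male animal is a candidate explanation. In Phlpp1 KO 1, which had little Xist and 0 counts of Y genes, the tables argue against 2 active X chromosomes, since the median X-linked gene differed by −0.003 on the log2 scale from the other 2 Phlpp1 knockout libraries. A single X chromosome is a candidate explanation there, since Kdm6a, Kdm5c, Ddx3x and Eif2s3x averaged −0.47 against those libraries. Both libraries follow their genotype labels in Phlpp1 and Phlpp2 (8.12 and 11.1 CPM in Phlpp1/2 KO 1, 9.25 and 24.9 in Phlpp1 KO 1), while an exchange with a sample of the same genotype was not tested, and the design names no biological difference here.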

How the results depend on the processing

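The removal of the 2 low-Xist libraries, protein-coding nuclear genes alone, the targeted gene left out of its window and the targeted genes left out of their list were chosen only after the results were seen. With 3 samples per group, leaving out 1 library leaves a pair in 1 group. The smallest simulated changes were found in 14% of genes by edgeR, so small changes are mostly missed. Counts of called genes depend on the processing, and except where stated the cause was not tested. In the order Phlpp1, Phlpp2 and Phlpp1/2 knockout against WT, Phlpp1/2 against Phlpp1, Phlpp1/2 against Phlpp2, Phlpp1 against Phlpp2 and interaction, the counts of 89, 20, 39, 2, 12, 25 and 8 became 461, 110, 102, 14, 32, 119 and 183 with no filter and 990, 317, 168, 21, 44, 176 and 650 with DESeq2. Of the genes given an adjusted p by DESeq2, it called 83 of 83, 18 of 18 and 37 of 37 of those called against WT. A threshold of 2-fold, which by construction lowers the count, left 23, 12, 17, 1, 3 and 11 in the first 6. Limma-voom called 13 for the Phlpp2 knockout, and library size alone 4 for Phlpp1/2 against Phlpp1. A replicate block gave 245 for the Phlpp1 knockout (166 higher, 79 lower), 84 for the Phlpp2 knockout (71 higher, 13 lower), 29 for the Phlpp1/2 knockout, 15 for Phlpp1 against Phlpp2 and 308 for the interaction (6 higher, 302 lower). The block ended 5 list calls: FGF and ERK feedback targets (adjusted p = 0.0870) and keratinocyte markers (0.0634) in the Phlpp1 knockout against WT, cell cycle in Phlpp1/2 against Phlpp2 (0.0814), and endothelial and macrophage markers in Phlpp1 against Phlpp2 (0.0555 each). Sample numbers were not taken to pair the samples: the deviations of libraries with the same number correlated at −0.156 to 0.302 (mean −0.003, 18 pairs), and 5 of 12 libraries correlated best on average with their own number. In all 4 genotypes, though, the ribosomal share was highest in replicate 2 and lowest in replicate 3, so a batch shared by number stays open. The 6 compared libraries alone gave 1163 for the Phlpp1 knockout, 1 for Phlpp1/2 against Phlpp1 and 3 for Phlpp1/2 against Phlpp2. Without genes within 20 Mb of the loci, which removes called genes by construction, Phlpp1/2 against Phlpp1 had 0 by edgeR, Phlpp1/2 against Phlpp2 had 1 and Phlpp1 against Phlpp2 had 12. Without the 2 low-Xist libraries, which leaves fewer samples, the Phlpp1 knockout had 18, Phlpp1/2 against Phlpp2 had 3, Phlpp1 against Phlpp2 had 11 and the interaction 4. Protein-coding nuclear genes alone gave 2 for the Phlpp2 knockout, 20 for the Phlpp1/2 knockout and 0 for the interaction by edgeR. Leaving out 1 library gave 16 to 57, 9 to 22, 18 to 34, 2 to 4, 4 to 132, 8 to 207 and 5 to 1196 in the order above. Called lists, 12, 5, 16, 12, 13, 12 and 3, became 0 in all 7 contrasts with an estimated correlation, and 0 with fry except for 6 in the Phlpp1/2 knockout against WT. They ranged from 7 to 14, 4 to 12, 16 to 20, 10 to 15, 7 to 17, 8 to 13 and 1 to 9 with 1 library left out, and the interaction had 5 without the low-Xist libraries. The list of PHLPP, AKT and substrate kinases lost its call in the 3 contrasts that had it once the targeted genes were left out (adjusted p = 0.448, 0.0786 and 0.418). Direction turned with 1 library left out for 3 lists: cell cycle in Phlpp1/2 against Phlpp2 without Phlpp2 KO 1 (adjusted p = 0.441, range 7.475e-06 to 0.441), and in Phlpp1 against Phlpp2 glycolysis and hypoxia without Phlpp2 KO 2 (0.959, range 8.832e-08 to 0.959) and endothelial markers without Phlpp1 KO 1 (0.990, range 1.83e-07 to 0.990). Shared calls of 15 for Phlpp1 and Phlpp2, 26 for Phlpp1 and Phlpp1/2 and 13 for Phlpp2 and Phlpp1/2 became 200, 106 and 57 with DESeq2, and 9 to 14, 13 to 19 and 8 to 14 with 1 WT library left out; knockout libraries were not left out for these. The odds ratio near Phlpp1 in the Phlpp1 knockout was 11.79 in a 5 Mb window (unadjusted exact p = 0.0868), where the only call was Phlpp1 itself (0 of 87 without it). In a 40 Mb window it fell to 4.74 (unadjusted exact p = 0.000251), or to 4.21 without Phlpp1 itself (unadjusted exact p = 0.0011). Near Phlpp2 it was 0 in a 5 Mb window in the Phlpp2 knockout. In the Phlpp1/2 knockout it was 3.39 in a 5 Mb window, where the only call was Phlpp2 itself (0 of 38 without it), 2.28 in a 40 Mb window, and 2.62 in the 20 Mb window without the targeted gene. Genes with small changes turned direction when 1 library was left out, none of them called in the full data. In the Phlpp1 knockout the log2 ranges were −0.15 to 0.023 for Phlpp2, −0.30 to 0.19 for Fgf18 and −0.15 to 0.15 for Col2a1. In the Phlpp2 knockout they were −0.0094 to 0.16 for Phlpp1, −0.35 to 0.036 for Sox9, −0.28 to 0.010 for Col2a1, −0.13 to 0.090 for Runx2 and −0.29 to 0.026 for Pth1r. In the Phlpp1/2 knockout they were −0.28 to 0.016 for Fgf18 and −0.052 to 0.13 for Mmp13, which was −0.040 without the low-Xist libraries. Fgf18 in the Phlpp1 knockout was −0.0013 with a CPM of at least 1 in 3 libraries, −0.0042 with library size alone and −0.05 with limma-voom. The last counts cover values of all called genes, of genes taken by the rule and of leading list members. Of these, 381 of 386 kept direction and side of the threshold with the size factors of DESeq2. Library size alone kept 363 of 386, the CPM filter 371 of 378 and limma-voom 345 of 386. The block kept 353 of 386, and leaving out 1 library kept 1715 of 2400, where 652 lost their call. Without the 2 low-Xist libraries 268 of 386 were kept, 117 lost their call and 1 turned direction.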

Other observations

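These genes were chosen after their values were seen, and no explanation was tested for them. On chromosome 12 between 72073428 and 73988966, L3hypdh, Dhrs7 and Snapc1 were low in the Phlpp1 knockout and lay between it and WT in the Phlpp1/2 knockout: Dhrs7 averaged 38.6, 20.1, 39.1 and 29.1 CPM and Snapc1 40.8, 21.2, 48.3 and 31.7 CPM in WT, Phlpp1, Phlpp2 and Phlpp1/2 knockout. The predicted gene 2410018L13Rik, which has near-identical copies, differed between libraries of 1 genotype: it was 2.93, 0.459 and 1.77 CPM in Phlpp1/2 KO 1, 2 and 3, and 0.289 to 0.364 CPM in the Phlpp2 knockout. The mitochondrial gene mt-Cytb was 1226 to 1273 CPM in WT, and was highest in Phlpp1 KO 3 (2245), Phlpp2 KO 3 (2233) and Phlpp1/2 KO 3 (1954).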
